A study of Mus musculus with 8 samples.

How the data were processed

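RNA from pancreatic islets of 10-week-old female NOD mice, a strain that develops autoimmune diabetes, was sequenced after treatment with vehicle or with PAHSA, palmitic acid esters of hydroxy stearic acids, a class of lipids. There were 4 vehicle and 4 PAHSA libraries. The design text speaks of 4 treated and 4 control mice, while the protocol in the labels speaks of 4 sets of islets pooled from 2 mice each. Whether a library stands for 1 mouse or for a pool of 2 was therefore left open, and p-values measure the spread between libraries. Vehicle libraries carry the numbers 1, 3, 4 and 5 and PAHSA libraries the numbers 1, 2, 3 and 4 in the labels.

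Total RNA was extracted with a column kit and libraries were made with the Nextera XT kit, per the labels' protocols. This kit does not mark the strand. The deposited values are log2 CPM, counts scaled by an effective library size, for 13725 Ensembl gene identifiers in 8 columns, and all 8 columns were matched to a library by name. The CPM of a library summed to between 965680 (PAHSA replicate 1) and 1069260 (vehicle replicate 4), so the scaling was not by the plain total. Percentages of CPM given below are taken on the CPM scale itself and not over that sum. Per the submitters' processing notes, kallisto and limma were used, and no version is stated there. The genome build and the annotation release are not given in the sources used here. kallisto shares reads between similar transcripts by a model, so values of near-identical genes, such as the trypsinogens, the amylases, Ins1 and Ins2, the Gstm family or the class II histocompatibility genes, are less certain than others, as are those of genes that overlap on opposite strands.

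The lowest value repeats within each column and lies below the next repeated value by the step that log2 CPM gives for 0 and 1 counts when 0.5 counts are added. From that step, estimated counts were recovered as a description of depth, from 34461742 to 45236238 per library. Between 47.8% and 51.5% of the recovered values lay within 0.01 of a whole number, so they were treated as estimated and not as read counts. In the deposited table every gene had at least 5 libraries at or above 0.258 CPM, and no gene was at the lowest value in more than 3 libraries, so a filter on low values had already been applied by the authors. Genes below that level, among them Cdkn2a and most lymphocyte markers, were not analysed here.

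Symbols and coordinates came from GENCODE release M21 (GRCm38) by Ensembl identifier, and 56 identifiers had no match and kept their identifier. Positions are those of GRCm38 in that annotation, not of the authors' build. Genes with a mean log2 CPM above 0 over all 8 libraries were tested, which kept 12231 genes and left out 1494. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with group as the only term, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are PAHSA minus vehicle on the log2 CPM scale, which understates the change of weakly expressed genes because of the added 0.5 counts. The SE and the 95% confidence interval of a fold change come from limma and the SD from the 4 libraries of a group.

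Before the data were examined, 24 gene lists with 489 entries were fixed, of which 339 entries were tested. They covered the Mdm2-p53 pathway, senescence markers and secreted factors, cell death, DNA damage response, cell cycle, beta cell identity and function, dedifferentiation and disallowed genes, ER stress and unfolded protein response, antioxidant response, oxidative phosphorylation, lipid metabolism and fatty acid receptors, interferon response and antigen presentation, and immediate early and handling stress. The others held markers of alpha cells, of delta and PP cells, of acinar cells, of duct cells, of T and NK cells, of B cells, of macrophages and dendritic cells, of endothelial cells, of stellate cells with fibroblasts and pericytes, of Schwann cells and of red blood cells. Some genes stand in more than 1 list. The 20 lists with at least 3 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and limma's fry were the alternatives. The mean log2 CPM of each list was also compared between groups by a two-sided exact permutation test over all 70 assignments of the 8 libraries, in which the smallest possible p is 0.0286, adjusted over the 20 lists.

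Named genes followed a rule fixed with the lists. It took the 8 genes with the largest positive and the 8 with the largest negative change among those past the threshold, filled up with the smallest unadjusted p where too few passed, without predicted genes, pseudogenes and RIKEN clones. It always took Trp53, Mdm2, Cdkn1a, Cdkn2a, Ins1, Ins2 and Gcg, and the 3 members with the smallest p of the Mdm2-p53, senescence, cell death and beta cell lists and of every other list that passed. Of the genes this rule took, 1 is not reported here. Genes outside this rule are named as chosen after their values were seen.

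The procedure was tested on simulated data with the spread of these libraries and 12231 genes. For the PAHSA and vehicle comparison it recovered 30 of 100 genes changed by 1 on the log2 scale and 71 of 100 changed by 2, with 6 unchanged genes called. A list of 29 genes shifted by 0.5 was called, and it was the only call among 20 lists. The simulated genes were drawn independently of each other. The simulation therefore says nothing about false list calls where the genes of a list vary together.

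Alternatives fixed beforehand were no filter, a mean log2 CPM above 2, log2(CPM + 1), centring each library on its median gene, quantile normalization, eBayes without trend or with robust estimation, limma's arrayWeights, the replicate number as a block, each library left out in turn, the acinar mean or the T, NK and B cell mean as a covariate, a threshold of 0.1, the estimated correlation, fry, and the median in place of the mean of a list. The T, NK and B cell covariate rested on 1 tested gene. Added after seeing the data were a fit on genes above the lowest value in every library, a fit without the libraries numbered 4, the stellate marker mean as a covariate and voom precision weights on the recovered estimated counts.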

Results

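Islet RNA from female NOD mice was compared between 4 PAHSA and 4 vehicle libraries. The study's title places the comparison in the context of cell senescence, of protection of beta cells from metabolic stress, and of the Mdm2 and p53 pathway. Recovered estimated counts ranged from 34461742 to 45236238 in the vehicle libraries and from 35356278 to 39359123 in the PAHSA libraries. The median SE of a log2 fold change was 0.25 and the median 95% confidence interval reached 0.55 to either side.

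In PAHSA libraries the acinar marker list was lower, by a mean of -2.32 on the log2 scale over 25 genes (-1.18 without PAHSA replicate 4), and so were the lists of senescence markers and secreted factors (mean -0.64 and median -0.19 over 23 genes) and of dedifferentiation and disallowed genes (mean -0.64 and median -0.42 over 11 genes). The list of beta cell identity and function was higher, by a mean of 0.17 over 30 genes, with Ucn3, a peptide hormone of mature beta cells, at 1.70-fold the vehicle level. Trp53 and its negative regulator Mdm2 had differences of 0.02 (SE 0.19) and -0.07 (SE 0.14). In limma, 0 of 12231 genes passed an adjusted p of 0.05, the smallest adjusted p was 0.671, and 894 genes had an unadjusted p under 0.05 where chance alone gives 611.6. Of these 894 genes, 369 were higher and 525 lower in PAHSA. Of the 20 lists tested, 9 passed by camera with the preset correlation, 0 with an estimated correlation and 0 by fry. The count was 3, 2, 3 and 4 without vehicle replicate 1, vehicle replicate 3, PAHSA replicate 1 and PAHSA replicate 3, 3 under quantile normalization and 4 with the stellate mean as a covariate. The values of single genes given here are differences that did not pass over all genes.

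The 8 higher genes with the smallest p included Gstm1, a glutathione transferase, at 7.64 ± 0.16 log2 CPM (SD, n = 4) in PAHSA and 6.93 ± 0.15 in vehicle, a difference of 0.71 (SE 0.12). Gstm1 (ENSMUSG00000058135) is a protein-coding gene on chromosome 3 from 108012255 to 108017973 in GRCm38. The alcohol dehydrogenase Adh1 differed by 0.63 (SE 0.11), Ucn3 by 0.77 (SE 0.15), the secreted glycoprotein gene Creg1 by 0.47 (SE 0.10) and Uap1l1 by 0.46 (SE 0.10). Hadh, a mitochondrial enzyme of fatty acid oxidation, differed by 0.42 (SE 0.09), the phosphatase gene Ptpn4 by 0.78 (SE 0.18) and Psd4 by 1.86 (SE 0.43). Among the 8 lower genes, Npas2, a transcription factor of the circadian clock, was at 1.82 ± 0.68 log2 CPM in PAHSA and 4.23 ± 0.67 in vehicle (SD, n = 4), a difference of -2.41 (SE 0.44). Npas2 (ENSMUSG00000026077) lies on chromosome 1 from 39193731 to 39363236. The others were Ssr1, a subunit of the translocon-associated complex of the endoplasmic reticulum, at -0.43 (SE 0.09), the kinase gene Pak3 at -0.66 (SE 0.13), Tdrd3 at -0.95 (SE 0.20), Erich3 at -1.02 (SE 0.22), the chloride transporter gene Clcn5 at -0.88 (SE 0.19), the lysosomal protease gene Lgmn at -0.48 (SE 0.11) and Tbl2 at -0.67 (SE 0.15). In these 16 genes the 4 PAHSA libraries lay on one side of the 4 vehicle libraries. Such a separation was found for 490 genes, 4.01% of those tested, where chance gives 2.86%.

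**Figure D1:**
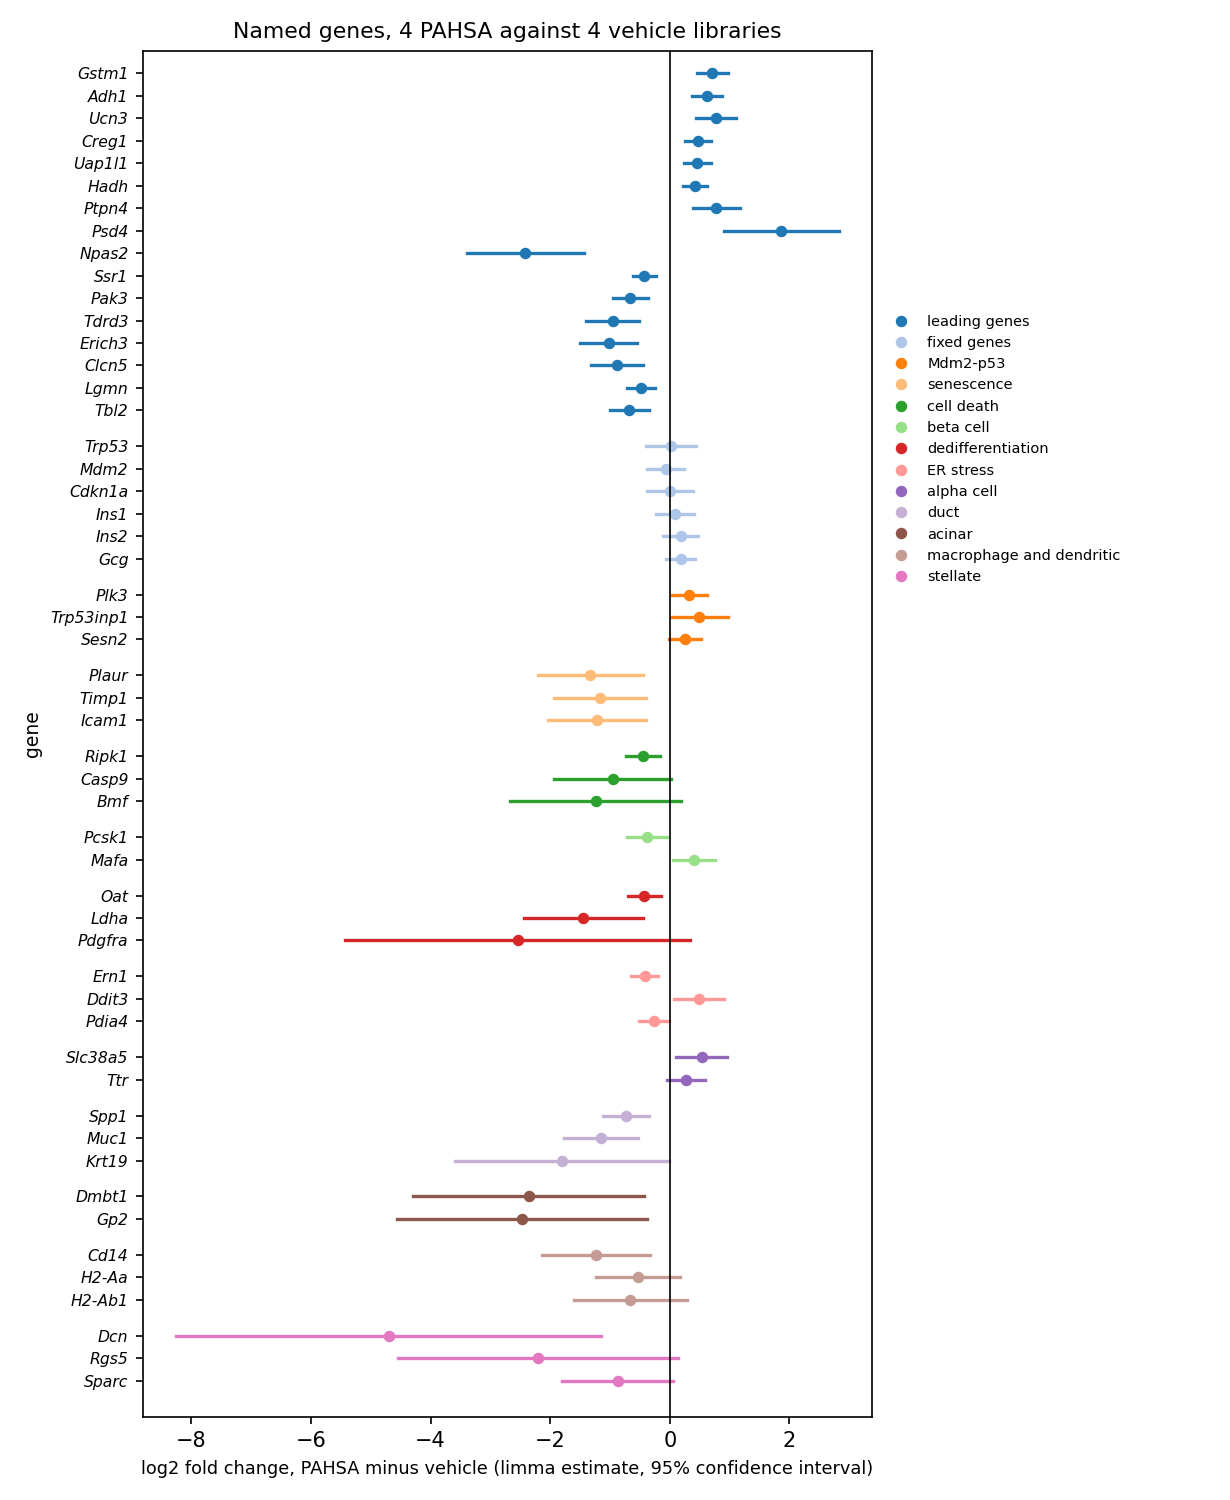
The x axis gives the log2 fold change of each named gene on the y axis, PAHSA minus vehicle over 4 libraries each, as the limma estimate (point) with its 95% confidence interval (line), coloured by the list or rule that named it. The intervals of Trp53, Mdm2 and Cdkn1a include 0, those of Plaur, Timp1 and Icam1 lie below 0, and no gene shown passed the adjusted threshold over all 12231 genes.

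Genes of the Mdm2-p53 pathway did not move as a group. Of 30 tested members, 16 were higher and 14 lower, and none passed over all genes or adjusted over the list alone. Trp53 (ENSMUSG00000059552, chromosome 11 from 69580359 to 69591873), which encodes p53, was at 5.01 ± 0.21 log2 CPM in vehicle and 5.02 ± 0.28 in PAHSA (SD, n = 4). Mdm2 (ENSMUSG00000020184, chromosome 10 from 117688875 to 117710758), which encodes the ubiquitin ligase of p53, was at 6.37 ± 0.14 and 6.30 ± 0.22, with a 95% confidence interval of the difference from -0.38 to 0.24. Cdkn1a (ENSMUSG00000023067, chromosome 17 from 29090976 to 29100727), the p53 target that encodes the cell cycle inhibitor p21, differed by 0.01 (SE 0.18). The signs of these 3 small differences changed with the scaling or the libraries used. The members with the smallest p were the p53 targets Plk3 at 0.33 (SE 0.13), Trp53inp1 at 0.49 (SE 0.22; 0.29 without vehicle replicate 4) and Sesn2 at 0.26 (SE 0.12). The list had an adjusted p of 0.580 by camera, and its mean of -0.007 and its median of 0.01 differ in sign, with the test pointing upward.

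The list of senescence markers and secreted factors fell in PAHSA by camera (adjusted p = 0.0155; adjusted p = 0.365 with an estimated correlation). Of its 23 tested members 16 were lower, 7 of them at an unadjusted p under 0.05, and 7 were higher, none at that level, while 0 passed over all genes and 0 adjusted over the list alone. Plaur, the urokinase receptor, differed by -1.33 (SE 0.40), Timp1, an inhibitor of matrix proteases, by -1.17 (SE 0.35) and Icam1, an adhesion molecule, by -1.22 (SE 0.37). Cdkn1a was not among the lower members, and Cdkn2a, which encodes p16, was not analysed here. The list mean was 4.53 ± 0.23 log2 CPM in vehicle and 3.89 ± 0.35 in PAHSA (SD, n = 4), with PAHSA replicate 4 at 4.41 inside the vehicle range of 4.26 to 4.73 (exact permutation p = 0.0571, adjusted 0.286). Stellate cell markers moved with this list, and with their mean as a covariate the list mean was -0.42 and the call was lost. The list stayed called at -0.36 over genes with a mean log2 CPM above 2, at -0.31 over genes above the lowest value in every library, at -0.41 on log2(CPM + 1), at -1.03 without a filter and at -0.97 with the acinar mean as a covariate. The call was also lost without vehicle replicate 1 (adjusted p = 0.0545), without vehicle replicate 3 (adjusted p = 0.0642) and without PAHSA replicate 2 (adjusted p = 0.0617).

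Cell death genes were not called by camera (adjusted p = 0.562), with 8 higher and 11 lower of 19 tested members, 1 of them lower at an unadjusted p under 0.05, and 0 past the threshold over all genes or adjusted over the list alone. Ripk1, a kinase of inflammatory cell death, differed by -0.45 (SE 0.13), Casp9 by -0.96 (SE 0.45; -0.48 without PAHSA replicate 4) and Bmf by -1.24 (SE 0.65; -0.77 without PAHSA replicate 3). The mean of this list barely separated the groups, at 4.03 ± 0.06 in vehicle and 3.87 ± 0.13 in PAHSA (SD, n = 4). The highest PAHSA library, replicate 2, was at 3.972 and the lowest vehicle library, replicate 5, at 3.974. The exact permutation p was 0.0286, the smallest possible, with an adjusted p of 0.286 over 20 lists. DNA damage response genes (10 higher and 8 lower of 18, camera adjusted p = 0.530) and cell cycle genes (6 higher and 4 lower of 10, camera adjusted p = 0.789) were not called either, with 0 genes past the threshold over all genes or adjusted over the list alone. For cell cycle genes the mean was -0.27, whereas the median of 0.10 and the test pointed upward.

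Genes of beta cell identity and function rose in PAHSA by camera (adjusted p = 0.00172; adjusted p = 0.335 with an estimated correlation). Of 30 members 22 were higher and 8 lower, 0 passed over all genes and 1 passed adjusted over the list alone. That gene was Ucn3 (ENSMUSG00000044988, chromosome 13 from 3940688 to 3945349), at 7.33 ± 0.20 log2 CPM in PAHSA and 6.57 ± 0.27 in vehicle (SD, n = 4; limma adjusted p over the list = 0.0121). Mafa, a transcription factor of mature beta cells, differed by 0.40 (SE 0.16), and the prohormone convertase gene Pcsk1 went the other way at -0.39 (SE 0.15; -0.24 without PAHSA replicate 1). The insulin genes Ins1 and Ins2 differed by 0.08 (SE 0.14) and 0.18 (SE 0.13), Ins2 by 0.27 without vehicle replicate 4. The difference of Ins1 changed sign in 3 of 23 alternatives. Ins2 took 8.38% ± 1.15 of CPM in vehicle and 9.47% ± 0.93 in PAHSA (SD, n = 4). The beta cell list was called in 23 of 25 alternatives, but not with an estimated correlation or by fry (adjusted p = 0.192). Those are the only alternatives without the preset correlation. The mean of the beta cell list had an exact permutation p of 0.0571 (adjusted 0.286). Acinar markers were lower on average in PAHSA, as given with the other cell types. With the acinar mean as a covariate the beta cell list was at 0.15 (camera adjusted p = 0.0194). With the stellate mean it was at 0.17 (camera adjusted p = 0.0137), both with the preset correlation.

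Dedifferentiation and disallowed genes, which mature beta cells keep low, fell by camera (adjusted p = 0.0336; adjusted p = 0.335 with an estimated correlation), with 8 lower and 3 higher of 11 tested members. None passed over all genes, and 2 passed adjusted over the list alone, Oat at -0.42 (SE 0.13), an enzyme of ornithine metabolism, and Ldha at -1.45 (SE 0.45; -0.89 without PAHSA replicate 1), lactate dehydrogenase. Pdgfra, which is also a marker in the stellate list, differed by -2.54 (SE 1.31). The mean of the dedifferentiation list had an exact permutation p of 0.114 (adjusted 0.327). The call was lost in 5 of 8 fits that left out 1 library, with adjusted p up to 0.171. Those were the fits without vehicle replicate 1, vehicle replicate 3 or PAHSA replicate 1, 2 or 3. The call was also lost with the stellate mean as a covariate (-0.18) and over genes with a mean log2 CPM above 2 (-0.34). Pdgfra stands both in this list and in the stellate mean, so the fit with that covariate is not independent of the list. On log2(CPM + 1) the mean was -0.36 and without the libraries numbered 4 it was -0.97, both still called, and with the median of the members per library in place of their mean the groups differed by 0.45, the other way (exact permutation adjusted p = 0.514). ER stress genes fell slightly by camera (adjusted p = 0.0230; adjusted p = 0.524 with an estimated correlation), with 20 lower and 9 higher of 29 members, a mean of -0.07 and a median of -0.15. None passed over all genes or adjusted over the list alone. The mean of the ER stress list had an exact permutation p of 0.429 (adjusted 0.612). Ern1, which encodes the stress sensor IRE1, differed by -0.42 (SE 0.10) and the chaperone gene Pdia4 by -0.26 (SE 0.11; -0.17 without PAHSA replicate 1), whereas Ddit3, which encodes the stress-induced factor CHOP, differed by 0.49 (SE 0.19; 0.32 without PAHSA replicate 1). Ddit3 was not alone among the 9 higher members, against 20 lower. Trib3 at 0.39 (SE 0.19), Atf3 at 0.34 (SE 0.31), Chac1 at 0.29 (SE 0.17) and Atf4 at 0.16 (SE 0.09) were higher too. These genes were named after their values were seen. The ER stress call was lost without vehicle replicate 3 (mean -0.05) and without PAHSA replicate 1 (-0.02) or 3 (-0.06), with adjusted p up to 0.210. The list stayed called at -0.14 without PAHSA replicate 4, at -0.13 without the libraries numbered 4, at -0.16 with the acinar mean as a covariate and at -0.13 with the T, NK and B cell mean. The call was also lost under quantile normalization, where the mean was 0.02, with the stellate mean as a covariate, where it was -0.01 (adjusted p = 0.600), and in eBayes without trend (adjusted p = 0.0813).

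The remaining functional lists were not called by camera, and 0 of their genes passed over all genes. Their camera adjusted p was 0.328 for antioxidant response (10 higher and 7 lower of 17), 0.517 for oxidative phosphorylation (12 higher and 9 lower of 21) and 0.328 for lipid metabolism and fatty acid receptors (15 higher and 12 lower of 27). Oxidative phosphorylation passed without vehicle replicate 4, at a mean of 0.07 (adjusted p = 0.0213). For interferon response and antigen presentation it was 0.789, with 13 higher and 15 lower of 28 members, a mean near 0 at 0.003, and a median of -0.14 in the direction of the test. For immediate early and handling stress genes it was 0.223, with 6 higher and 10 lower of 16. In that list 2 genes passed adjusted over the list alone, Zfp36 at -0.55 (SE 0.14) and Ier3 at -0.88 (SE 0.24), both named after their values were seen. In the other 4 of these lists 0 genes passed adjusted over the list alone.

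By camera with the preset correlation, markers of exocrine and stromal cells were lower in PAHSA and markers of alpha cells higher. The acinar list, enzymes and other products of the digestive gland around the islets, fell by camera (adjusted p = 2.29e-15; adjusted p = 0.439 with an estimated correlation). All 25 tested members were lower, 19 of them at an unadjusted p under 0.05, with 0 past the threshold over all genes and 0 adjusted over the list alone. Dmbt1, a secreted glycoprotein gene, differed by -2.36 (SE 0.88) and the zymogen granule protein gene Gp2 by -2.47 (SE 0.94). PAHSA replicate 4 was lowest for both, at 2.73 and 2.83 log2 CPM against 4.57 to 7.51 and 5.76 to 8.33 in the other PAHSA libraries, and without it the differences were -1.48 and -1.39. The list mean was -1.18 without PAHSA replicate 4 and -0.79 without the libraries numbered 4, and the list was called in both. Acinar genes took 1.44%, 1.46%, 5.73% and 3.58% of CPM in vehicle replicates 1, 3, 4 and 5, and 0.503%, 2.19%, 1.30% and 0.0527% in PAHSA replicates 1, 2, 3 and 4. The groups overlapped in the list mean (exact permutation p = 0.114, adjusted 0.327).

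**Figure D2:**
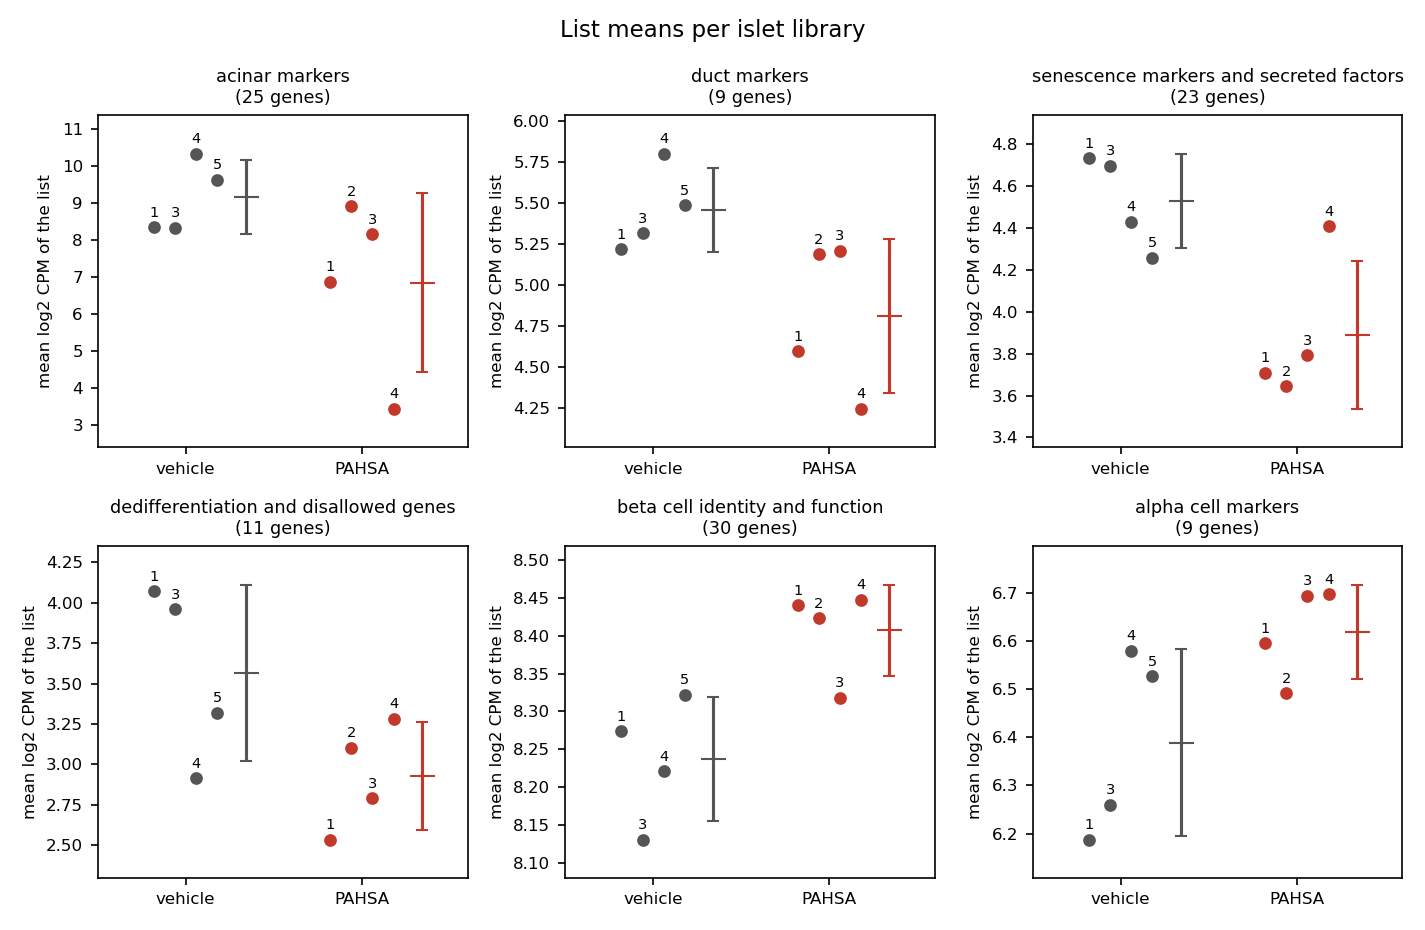
Each panel gives the mean log2 CPM of a gene list (y axis) in the 4 vehicle and 4 PAHSA libraries (x axis), with points numbered by replicate and bars for the group mean ± SD. The y axes differ between panels and do not start at 0; the acinar mean reaches from 3.43 in PAHSA replicate 4 to 10.3 in vehicle replicate 4, and the beta cell mean from 8.13 to 8.45.

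The duct list fell by camera (adjusted p = 0.0443; adjusted p = 0.335 with an estimated correlation), with 6 lower and 3 higher of 9 members and 0 past the threshold over all genes. Adjusted over the list alone 2 passed, the secreted phosphoprotein gene Spp1 at -0.73 (SE 0.17) and the mucin gene Muc1 at -1.15 (SE 0.28). Krt19, a duct keratin, differed by -1.80 (SE 0.81; -1.03 without PAHSA replicate 4). The duct list mean barely separated the groups, at 5.46 ± 0.26 in vehicle and 4.81 ± 0.47 in PAHSA (SD, n = 4). The highest PAHSA library, replicate 3, was at 5.211 and the lowest vehicle library, replicate 1, at 5.220. The exact permutation p was 0.0286, the smallest possible, with an adjusted p of 0.286. With the acinar mean as a covariate the duct list was at -0.20 (camera adjusted p = 0.633), and without the libraries numbered 4 at -0.34 (adjusted p = 0.399), so that the call was lost in both. It was also lost without vehicle replicate 1, 3 or 4 and without PAHSA replicate 1 or 4, with adjusted p up to 0.147.

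Stellate cell, fibroblast and pericyte markers fell by camera (adjusted p = 0.0230; adjusted p = 0.443 with an estimated correlation), with 8 lower and 3 higher of 11 members. The collagen-binding proteoglycan gene Dcn differed by -4.70 (SE 1.61). It was at -4.61, 3.47, -4.73 and -0.09 log2 CPM in PAHSA replicates 1, 2, 3 and 4, against 2.26 to 4.22 in vehicle. PAHSA replicates 1 and 3 lay near the lowest values of their libraries, -6.19 and -6.31, and PAHSA replicate 2 within the vehicle range. The pericyte gene Rgs5 differed by -2.20 (SE 1.06, and -1.42 without PAHSA replicate 2). The matrix protein gene Sparc differed by -0.87 (SE 0.42, and -0.54 without vehicle replicate 1). Macrophage and dendritic cell markers fell as well (adjusted p = 0.0485; adjusted p = 0.443 with an estimated correlation), with 6 lower and 1 higher of 7 members, among them the endotoxin receptor gene Cd14 at -1.23 (SE 0.41) and the class II histocompatibility genes H2-Aa at -0.53 (SE 0.32; -0.22 without PAHSA replicate 1) and H2-Ab1 at -0.66 (SE 0.43; -0.34 without vehicle replicate 1 and -0.37 without PAHSA replicate 1). Both lists had 0 genes past the threshold over all genes and 0 adjusted over the list alone. By list mean the exact permutation p was 0.229 for stellate and 0.2 for macrophage markers, both 0.468 adjusted. The stellate mean was -1.06, and the call was lost without vehicle replicate 1 (-0.62) or 3 (-0.83) and without PAHSA replicate 1 (-0.79) or 3 (-0.86), with adjusted p up to 0.250, while it stayed called at -1.78 with the acinar mean as a covariate and at -1.76 without the libraries numbered 4. The macrophage call was lost without vehicle replicate 1, 3 or 4 and without PAHSA replicate 1 or 3 (adjusted p up to 0.307), with a mean of -0.43 over all libraries and of -0.23 without PAHSA replicate 1. With the stellate mean as a covariate the macrophage mean was -0.13 and the call was lost (adjusted p = 0.659), and with the replicate number as a block it was -0.66 and called.

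Alpha cell markers rose by camera (adjusted p = 0.0443; adjusted p = 0.443 with an estimated correlation), with 7 higher and 2 lower of 9 members and 0 past the threshold over all genes or adjusted over the list alone. The amino acid transporter gene Slc38a5 differed by 0.53 (SE 0.19), the transthyretin gene Ttr by 0.28 (SE 0.14; 0.18 without vehicle replicate 1) and the glucagon gene Gcg by 0.18 (SE 0.11). The mean of the alpha list had an exact permutation p of 0.114 (adjusted 0.327). The alpha call was lost in 5 of 8 fits without 1 library, those without vehicle replicate 1 or 3 or PAHSA replicate 1, 3 or 4 (adjusted p up to 0.239). It was also lost with the stellate mean as a covariate, where the list mean went from 0.23 to 0.11 (adjusted p = 0.601), and with the acinar mean, where it was 0.25 (adjusted p = 0.119). Markers of delta and PP cells (1 higher and 5 lower of 6, camera adjusted p = 0.328) and of endothelial cells (0 higher and 5 lower of 5, camera adjusted p = 0.215) were not called, and 0 of their genes passed over all genes or adjusted over the list alone. The T and NK cell list kept 1 tested gene, Lck, at -1.03 (SE 0.63), and the Schwann cell list 1, S100b, at -0.92 (SE 0.72), both the sole members left. The B cell and red blood cell lists kept 0 tested genes, so these 4 lists were not tested and infiltration by lymphocytes was not analysed here.

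PAHSA libraries held more weakly measured genes. Genes with fewer than 10 estimated counts numbered 324.5 ± 108.9 in vehicle and 576.5 ± 45.4 in PAHSA (SD, n = 4), from 248 to 486 and from 543 to 642 (exact permutation p = 0.0286, the smallest possible, adjusted 0.248 over 13 library measures). Libraries of the same group correlated across genes with a median r of 0.904 in vehicle and 0.851 in PAHSA, against 0.876 between groups, where genes are not independent replicates. The first principal component held 21.8% of the variance, with PAHSA replicate 4 at 86.9 and vehicle replicate 4 at -50.3 at its ends.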

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

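Of the tests in this part, those of stellate content, of all non-endocrine cells together and of scatter between libraries, the bound that decides on acinar content in the senescence list, and the count of splits for genes past the adjusted threshold were chosen only after the result was seen. The fit with the acinar mean as a covariate was fixed beforehand.

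Of 156 groups of 4 libraries examined for a library far from the other 3, 8 had one, and chance gives about 1 in 20, or 7.8. PAHSA replicate 1 was low for Psd4, at 3.08 log2 CPM against 4.41 to 4.63 in the others. Vehicle replicate 3 was high for Erich3, at 6.40 against 5.76 to 5.81. Vehicle replicate 4 was high for Ins1, at 15.1 against 14.6 to 14.7, for Ins2, at 16.6 against 16.2 to 16.3, for the Ins2 share of CPM, at 10.1% against 7.65% to 7.92%, and for genes under 10 estimated counts, at 486 against 248 to 287. PAHSA replicate 1 was low in the mean of the interferon list, at 4.40 against 4.80 to 4.83, and PAHSA replicate 4 in that of the immediate early list, at 6.23 against 6.31 to 6.32.

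For genes past the adjusted threshold in limma the real split had 0 and the highest of the others 0, so the splits say nothing about chance there. For genes at an unadjusted p under 0.05, 2 of the 35 splits of the 8 libraries into 4 and 4 gave at least as many as the real one, which had 894, and the highest of the others was 895, so chance is not excluded for that count. That other split exchanges the libraries numbered 4 between the groups. For gene lists past the threshold, 1 of 35 splits, the real one, gave as many as 9, and the highest of the others was 7. That share, 0.0286, is the smallest the splits can give and was not adjusted over the counts examined. With an estimated correlation and in fry the real split had 0 lists, so chance is not excluded for that count.

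The lower acinar list in PAHSA may reflect exocrine tissue carried along with the islets. Within groups, 96.7% of the variance of the 25 acinar genes lay in 1 component, so the genes went up and down together from library to library. Differing amounts of 1 cell type would give this, but so would a joint change within acinar cells, so the share does not favour carry-over. PAHSA replicate 4 lay farthest from its group, at a list mean of 3.43 against 6.86 to 8.91 in the other PAHSA libraries. A lower share of all non-endocrine cells together was neither shown nor excluded. Within groups the acinar and stellate means had a Pearson r of -0.569 (exact permutation p = 0.0990) and a Spearman rho of -0.548 (exact permutation p = 0.120) over 8 libraries. Without vehicle replicates 1 and 4, the 2 libraries farthest in the stellate mean within groups, r was -0.525. PAHSA replicate 4, the lowest in the acinar mean, was kept for that value. An effect of PAHSA on acinar cells stays open and was not tested apart from carry-over.

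The lower senescence list may depend on which cells the preparations held. Acinar content as the whole cause is argued against, since with the acinar mean as a covariate the list mean moved from -0.64 (SE 0.21) to -0.97 (SE 0.12) and the list stayed called. Stellate and fibroblast content stays open. Within groups the senescence and stellate means had a Pearson r of 0.716 (exact permutation p = 0.0608) and a Spearman rho of 0.738 (exact permutation p = 0.0608) over 8 libraries. Without vehicle replicates 1 and 4, the 2 farthest in the stellate mean within groups, r was 0.744. With the stellate mean as a covariate the list mean was -0.42 (SE 0.19), 65.7% of its size without it, and the call ended with a smaller difference and an SE no larger than before. Whether the smaller difference alone ended it was not tested. A direct effect of PAHSA on these genes stays open as well, and these 2 relations between list means were the only ones computed in this family, with the smaller p at 0.0608 before adjustment.

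The larger number of weakly measured genes in PAHSA libraries is not likely to come from depth. After rounding to whole counts and thinning every library to the total of the smallest one, then 34461720, PAHSA libraries still had 235.3 more genes under 10 counts on average, against 252 before. More scatter between PAHSA libraries stays open, as the median SD of genes with a mean log2 CPM above 4 was 1.12 times that of vehicle. Library preparation and the animals cannot be told apart as its source, because each library is 1 preparation. An effect of treatment stays open and was not tested.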

How the results depend on the processing

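The fits on genes above the lowest value, without the libraries numbered 4, with the stellate covariate and with voom weights were chosen after seeing the data. All alternatives gave 0 genes past the threshold in limma, with 669 to 1021 genes at an unadjusted p under 0.05, and 0 lists passed by list mean in any setting. The smallest possible p of that exact permutation test, 0.0286, cannot pass over 20 lists unless many lists separate the groups at once. Of 53 named genes, 49 kept their sign in all settings. Quantile normalization gives Ins2 and Gcg the same value in every library, and a list was not fitted with its own mean as a covariate, so these have no value. Causes were not tested except where a fit used fewer libraries or genes.

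Camera calls fell from 9 to 3 under quantile normalization, to 4 with the stellate covariate, and to 0 with the estimated correlation and with fry, where the list means are those of the unaltered fit: acinar -2.32, stellate -1.06, duct -0.65, senescence -0.64, dedifferentiation -0.64, macrophage -0.43, ER stress -0.072, beta 0.17 and alpha 0.23. Calls were lost for duct (-0.65) and macrophage (-0.43) markers without a filter, for dedifferentiation (-0.34), alpha (0.21) and duct (-0.47) above a mean log2 CPM of 2, for alpha (0.21) on log2(CPM + 1), for alpha (0.22), duct (-0.66) and macrophage (-0.44) after centring, for ER stress (-0.072), duct (-0.65) and macrophage (-0.43) without trend, and for duct (-0.55) and macrophage (-0.43) with arrayWeights. Quantile normalization lost dedifferentiation (-0.43), ER stress (0.022, with the test still downward), alpha (0.26), duct (-0.53), macrophage (-0.42) and stellate (-0.82). The acinar covariate lost alpha (0.25) and duct (-0.20), the T, NK and B cell covariate, which rests on 1 gene, lost dedifferentiation (-0.83), alpha (0.24) and duct (-0.55). The stellate covariate lost senescence (-0.42), dedifferentiation (-0.18), ER stress (-0.012), alpha (0.11) and macrophage (-0.13), the fit without the libraries numbered 4 lost duct (-0.34), and voom weights lost macrophage (-0.40).

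Without 1 library at a time, 2 to 9 lists passed, lowest without vehicle replicate 3, with 3 without vehicle replicate 1 or PAHSA replicate 1 and 4 without PAHSA replicate 3. List means ranged from -3.01 to -1.18 for acinar and 0.13 to 0.20 for beta, both called in all 8 fits, from -0.81 to -0.56 for senescence, -0.85 to -0.47 for dedifferentiation, -0.14 to -0.025 for ER stress, 0.16 to 0.30 for alpha, -0.78 to -0.46 for duct, -0.60 to -0.23 for macrophage and -1.45 to -0.62 for stellate. Signs were unstable for Trp53 (-0.066 to 0.15), Mdm2 (-0.15 to 0.021), Cdkn1a (-0.12 to 0.13) and Ins1 (-0.00044 to 0.20), and for the lists Mdm2-p53 (-0.034 to 0.028), cell cycle (-0.38 to -0.10, where the test turned), oxidative phosphorylation (-0.026 to 0.072), interferon (-0.14 to 0.13) and antioxidant (-0.013 to 0.088).

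Oxidative phosphorylation passed upward without vehicle replicate 4, with the acinar covariate and without the libraries numbered 4, and delta and PP markers passed downward with the stellate covariate. Other settings turned directions. Centring gave Cdkn1a -0.0066, oxidative phosphorylation -0.0015 and interferon -0.0098. Quantile normalization gave delta and PP -0.029 with an upward test. The acinar covariate gave antioxidant -0.071, Trp53 -0.081, Mdm2 0.021 and Cdkn1a -0.17. The T, NK and B cell covariate gave interferon 0.041, delta and PP 0.026 and Mdm2 0.021. The stellate covariate gave cell cycle -0.26, oxidative phosphorylation -0.044, interferon 0.18, Trp53 -0.067, Cdkn1a -0.086 and Ins1 -0.021, and Cdkn1a was -0.0073 without the libraries numbered 4. The median in place of the mean of a list gave cell cycle 0.22, dedifferentiation 0.45, interferon -0.14, immediate early 0.0023 and endothelial 0.083.

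No pairing by replicate number showed in the values. Libraries numbered 1, 3 and 4 in both groups had correlations of deviations of -0.020, -0.017 and -0.022, and in none of the 3 was the own number the best partner. The labels do not state a pairing, and these correlations cannot exclude one. With the replicate number as a block, 0 genes, 747 genes at an unadjusted p under 0.05 and 9 lists passed. Oxidative phosphorylation (-0.031), delta and PP (0.043) and Ins1 (-0.045) changed direction in that paired fit.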

Other observations

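The lists of this part were written after the gene results had been seen, without the genes that prompted them, and each was tested after that. They were prompted by the lower values of Ldha, Hilpda, Fam162a and Gys1, of the clock gene Npas2 and of Icam1 and Plaur, and 3 exact permutation tests were run, with camera on the 4 lists beside them.

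Genes induced by low oxygen had lower values in PAHSA. Of 27 genes written down, 25 were tested and all 25 were lower, 17 of them at an unadjusted p under 0.05 and 0 past the adjusted threshold over all genes in limma. The members with the smallest p were Bnip3, which encodes a protein of mitophagy, at -0.70 (SE 0.18), the glycolysis enzyme gene Eno1 at -0.56 (SE 0.16) and P4ha1, a collagen hydroxylase gene, at -0.52 (SE 0.15). Glycolysis genes made up a good part of the list, among them Pgk1 at -0.69 (SE 0.20), Gapdh at -0.42 (SE 0.14) and Tpi1 at -0.43 (SE 0.13), named after their values were seen. The list mean was 7.13, 7.31, 7.05 and 7.13 log2 CPM in vehicle replicates 1, 3, 4 and 5, and 6.13, 6.50, 6.46 and 7.11 in PAHSA replicates 1, 2, 3 and 4, so that PAHSA replicate 4 lay within the vehicle range. The stellate list mean ranked the PAHSA libraries in the same order, at 0.96, 2.21, 1.17 and 2.71 in the same replicates. In vehicle replicates 1, 3, 4 and 5 it was 4.12, 3.49, 1.66 and 2.01, in another order.

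The hypothesis was lower hypoxia-induced expression in PAHSA islets, which restates the lower values and gives no cause for them. The list mean differed by -0.61 with an exact permutation p of 0.0571, adjusted 0.129 over the 3 tests, so the hypothesis was not settled by the test chosen for it. Camera gave an adjusted p of 4.14e-16 with the preset correlation and of 0.0871 with an estimated correlation, adjusted over the 4 lists of this part. Whether such a difference would come from treatment or from handling of the islets could not be tested. No fit with a marker mean as a covariate was made for this list, so the cell content of the preparations stays open as well.

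A different clock phase at collection might lower Npas2. Genes with their peak near that of Npas2 would then be lower (4 tested, mean -0.06) and genes opposite in phase higher (10 tested, 9 higher, mean 0.29). The difference of both means was -0.34 with an exact permutation p of 0.229, adjusted 0.229, which leaves this open. Camera adjusted p was 0.826 and 0.0638 for these lists, and 0.835 and 0.148 with an estimated correlation.

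Lower expression of NF-kB targets might go with lower Icam1 and Plaur. Of 23 tested genes, among which Sod2 and Fas also stand in lists fixed earlier, 20 were lower and 3 higher, 1 of them at an unadjusted p under 0.05. The list mean differed by -0.34 with an exact permutation p of 0.0857, adjusted 0.129 over the 3 tests, and camera adjusted p was 0.0112, or 0.0871 with an estimated correlation. The test did not settle this hypothesis either.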
